A study of Danio rerio with 8 samples.

How the data were processed

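Bulk RNA-seq was made from tcf21:nEGFP-positive epicardial cells sorted from ventricles of juvenile zebrafish, with 4 libraries from cxcr4a mutants (cxcr4aum20) and 4 from wild type. The sample titles write the reporter as Tcf21:nGFP. RNA from sorted cells was amplified with SMART-Seq v4 and made into libraries with Nextera XT, per the labels' protocols. That chemistry does not mark strand, so reads of a gene and of an overlapping antisense gene cannot be told apart. The reads were processed with cutadapt 5.2, STAR 2.7.11a and HTSeq on GRCz11, per the submitters' processing notes; their parameters, the HTSeq version and the annotation release are not given in the sources used here. The deposited values are whole-number read counts per gene symbol, not normalized, for 53709 symbols per library. Reads assigned to no gene are not analysed here, so their share, planned as a library measure, was not computed.

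Of the 53709 symbols, 16024 carry an added number (_1, _2 and so on) and the plain symbol is present for every one of them, so 6260 symbols occur on more than 1 row. They are called repeated symbols here, and their rows are called copies. What separates the copies in the annotation used for counting is not given in the sources used here, so counts of single copies are uncertain where reads could be placed on either. All tests used the rows as deposited. As an alternative chosen after seeing the data, copies of a symbol were summed before the fit.

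Genes were compared with edgeR 4.0.16 in R 4.3.3 (filterByExpr, TMM normalization, quasi-likelihood F-test, 2-sided) with genotype as the only term and all 8 libraries in the fit. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Standard errors of log2 fold changes were taken from the F statistic. Levels are CPM scaled with TMM factors, as mean ± SD over 4 libraries. For a gene with no counts in a group, the fold is a lower bound computed from a floor of 3 counts over the group. For 1 to 3 counts, the ratio is given with an exact binomial 95% interval. Intervals and floors cover counting error only, since amplified reads without molecular identifiers are not independent molecules.

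Gene lists, 31 in number with 1251 symbols, were written before the data were examined; 1233 of the symbols matched a row. They were tested with camera from limma 3.58.1 with a preset correlation between genes of 0.01, and adjusted over the 31 lists. Camera with an estimated correlation and fry were run beside it. A list's score in a library is the mean log2 CPM (prior count 2) of its tested members. Library measures and scores were compared by an exact permutation test, 2-sided, over the 70 assignments of 8 libraries, whose smallest p is 0.0286. Chromosome membership and neighbourhood of genes came from a RefSeq table of the GRCz12tu assembly, which differs from the build of the counts, so no coordinate is given. It placed 95.7% of tested genes, and called genes were compared by Fisher's exact test on the chromosome of cxcr4a and within 10 Mb of it. A suffixed copy took the position of its plain symbol, so its own location was not established.

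Genes are named by a rule fixed before the data were examined. It takes a panel of 15 genes around cxcr4a, the epicardium and its neighbours, and up to 4 members of each list with the smallest p. It also takes, per direction, the 8 called genes with the smallest p and the 4 with the largest change at a mean log2 CPM of 3 or more, if the groups did not overlap and the symbol was not clone-based. Other genes named were chosen after their values were seen. Alternatives were DESeq2 1.42.0, limma voom with and without quality weights, DESeq2 size factors, library size only, other low-count filters, a fold threshold of 1.2, the replicate number as a block, and leaving out each library in turn. Summed copies, no mitochondrial genes, and the lists without cxcr4a mutant 1 and 2 were added after seeing the data.

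The edgeR and camera steps were tested on simulated counts drawn from the real means and dispersions, with 200 of 18002 genes changed in each of 3 simulations. For cxcr4a mutant against wild type, 1.49% of simulated genes changed 2-fold were called, 31.3% of those changed 4-fold and 53.0% of those changed 8-fold. Of 178 simulated calls, 7 were false. The 3 lists that were shifted were each called, and 1 list that was not shifted was called too. Simulated genes varied independently, so the list calls were not tested under correlation between genes. The labels do not say whether the libraries of a group came from separate fish or pools, so p-values measure the spread between these libraries, which may be partly technical. No pair of libraries agreed within sampling noise.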

Results

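Epicardial cells form the outer layer of the heart and can be marked by the tcf21 reporter used for this sort. They were collected from ventricles of zebrafish aged 70 days, from wild type and from mutants of cxcr4a, a chemokine receptor gene, which the labels describe as having lost coronary vessels. The comparison asks how epicardial transcription differs between mutants described as lacking these vessels and wild type. It cannot tell the loss of vessels apart from other effects of the mutation. The 4 mutant libraries held 18891079 to 25513003 counts and the 4 wild-type libraries 19584695 to 28471786. Between 16624 and 18902 genes per library had a count of 10 or more.

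cxcr4a, the mutated gene, was weakly counted in every library. It had 86, 229, 171 and 447 counts in mutant libraries 1 to 4 and 219, 12, 118 and 27 in wild-type libraries 1 to 4. Its log2 fold change was 1.24 ± 0.85 (SE, n = 4 per group; edgeR adjusted p = 0.668). These counts do not check the genotype labels, because a mutant transcript can still be counted. The paralog cxcr4b did not differ (log2 fold change -0.14 ± 0.82, edgeR adjusted p = 0.977), and its lowest value, 245 counts, was in cxcr4a mutant 2. The ligand gene cxcl12a was at 229 ± 87.9 CPM in mutants and 90 ± 20.4 CPM in wild type (SD, n = 4), above every wild-type library in 4 of 4 mutants. Its log2 fold change of 1.35 ± 0.29 did not pass over all genes (edgeR adjusted p = 0.102) but did when adjusted over the list alone (0.0212 in chemokines and receptors). For the second ligand gene, cxcl12b, the plain copy was at -2.05 ± 0.55 (edgeR adjusted p = 0.183) and the sum of its copies at -0.85 ± 0.45 (edgeR adjusted p = 0.650).

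Of 18002 genes tested with edgeR, 63 were called, 25 higher and 38 lower in cxcr4a mutants, and 1951 had an unadjusted p under 0.05. Of the 63, 24 had 3 or fewer counts in a whole group. Groups did not overlap for 1511 genes, 8.39% of those tested against 2.86% by chance. The chemokine receptor gene ccr11.1 fell from 47.0 ± 13.8 CPM in wild type to 0.0640 ± 0.0986 CPM in mutants (SD, n = 4), with 7 counts in all 4 mutant libraries (log2 fold change -9.22 ± 0.77, edgeR adjusted p = 0.00362). mhc2dhb, an MHC class II gene, which presents antigen, fell 21.2-fold, from 68.7 ± 21.0 to 3.23 ± 1.75 CPM (edgeR adjusted p = 0.0123). parp14rs4 had 2 counts in mutants and 828 in wild type, a ratio of 388 (95% counting interval 107 to 3210; edgeR adjusted p = 0.00985). fbn1, which encodes the microfibril protein fibrillin, rose from 55.1 ± 9.43 to 126.7 ± 11.14 CPM (edgeR adjusted p = 0.0442). The fbn1 call was lost when any of the 8 libraries was left out, with log2 fold changes of 1.11 to 1.28. Genes called after leaving out 1 library numbered 43 without cxcr4a mutant 2 and 16 to 38 without each of the other 7 libraries.

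Most genes called by edgeR, 41 of 63, were copies of repeated symbols, which made up 21.1% of tested genes (Fisher's exact odds ratio 7.03, 95% interval 4.08 to 12.4, p = 5.9e-14). Among the 901 genes called by DESeq2 their share was 44.7%. DESeq2 tested 29165 rows, without filterByExpr, and the share of repeated symbols among those was not computed. The 44.7% therefore cannot be set against the 21.1%. bmp2k, a kinase gene, rose from 15.8 ± 2.90 to 58.3 ± 13.7 CPM (edgeR adjusted p = 0.0190), while its copy bmp2k_1 fell from 39.8 ± 8.82 to 2.09 ± 0.693 CPM (edgeR adjusted p = 0.00362). The sum of both copies differed by only 0.13 ± 0.22 on the log2 scale (edgeR adjusted p = 0.925). Similar pairs were tspan4b, which fell by 3.13 as a single copy and was at -0.34 ± 0.21 when summed, and ubtd2_1, with 1 count in mutants and 707 in wild type and a summed change of -0.01 ± 0.23. For rpia, a pentose phosphate enzyme gene, the plain copy had 0 counts in wild type and was at least 217-fold higher in mutants, and the summed gene was at -0.21 ± 0.32. The called copies rimkla, antxr2a_1, gstt1b_1, eif2ak3, lamtor5, itsn2b_1, srgn, neu3.5 and tiparp_1 likewise did not pass as summed genes. Among them, tiparp was at 1.31 ± 0.45 and neu3.5 at 2.16 ± 0.45 after summing (edgeR adjusted p = 0.455 and 0.156). clic2_2 fell from 55.3 ± 24.0 to 1.57 ± 1.36 CPM (edgeR adjusted p = 0.0255), and the summed gene was at a similar -5.06 ± 0.74 without passing (edgeR adjusted p = 0.0719).

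**Figure D1:**
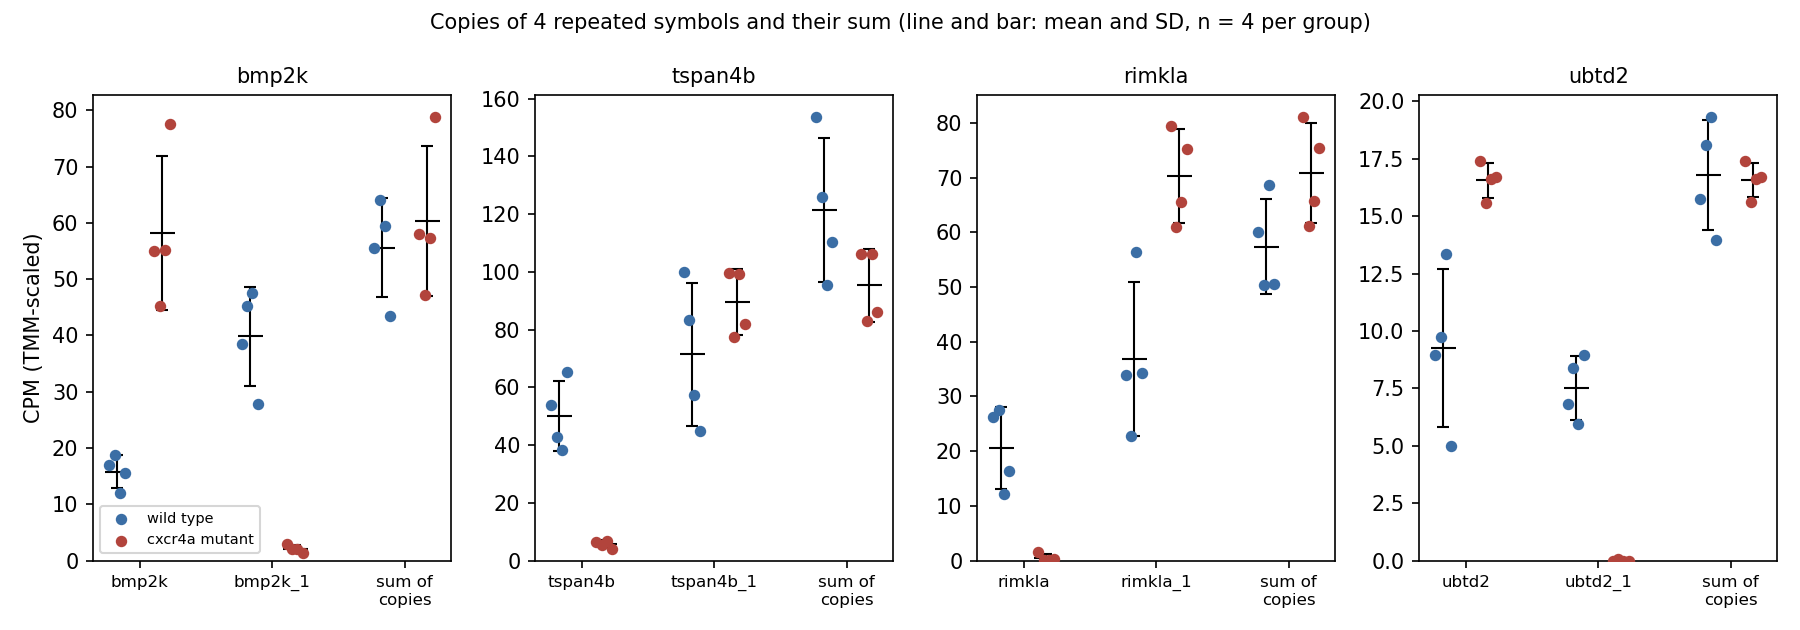
CPM of single copies and of their sum for bmp2k, tspan4b, rimkla and ubtd2, 1 point per library, with mean and SD of 4 libraries per group. The copies bmp2k_1 and ubtd2_1 were below every wild-type library in all 4 mutants, while the sums of copies overlapped between groups.

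With copies summed, 8 of 16631 symbols were called by edgeR, and all 8 were also among the 63. ccr11.1, mhc2dhb and parp14rs4 were among the 6 lower symbols. The other 3 lower symbols, named after their values were seen, were fthl31, a ferritin-like gene at 25.1 ± 4.78 CPM in wild type and 4.73 ± 1.19 CPM in mutants, LOC567883 and LOC137489911. The 2 higher symbols, also named after their values were seen, were zgc:112970, with 0 counts in wild type and at least 292-fold higher in mutants, and LOC101882642, with 917 counts in mutants and 2 in wild type. At an adjusted p under 0.10 that fit had 19 symbols. aspn, a small matrix proteoglycan gene named after its values were seen, was among the 63 as deposited (log2 fold change 4.49 ± 0.74, edgeR adjusted p = 0.0442). In the summed fit, at 13.7 ± 10.6 CPM in mutants and 0.598 ± 0.394 CPM in wild type, it did not pass (edgeR adjusted p = 0.102). abca1a, a cholesterol exporter gene, passed in neither fit and in the summed one was at 283 ± 89.6 and 93.9 ± 16.6 CPM (edgeR adjusted p = 0.137).

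Genes induced by low oxygen were higher in cxcr4a mutants as a list. Of 37 tested members, 34 had a positive log2 fold change, with a median of 1.02, and the camera adjusted p was 1.7e-09. With an estimated correlation the call was lost (adjusted p = 0.589 with an estimated correlation). The hypoxia score was 5.87 ± 0.57 in mutants and 4.56 ± 0.27 in wild type (SD, n = 4), above every wild-type library in 4 of 4 mutants, with an exact permutation p of 0.0286, the smallest possible, and 0.221 after adjustment over 31 scores. The glycolysis list shares 12 tested members with it and had 32 of 34 positive changes (median 1.00, camera adjusted p = 7.3e-08; adjusted p = 0.589 with an estimated correlation). Adjusted over the list alone, 1 hypoxia gene and 3 glycolysis genes were called higher, against 1 in each over all genes, which was hk2 in both. DESeq2 called 5 members of each over all genes. The plain copy of hk2, encoding hexokinase, had 663 counts in mutants and 5 in wild type, but its copies summed to a log2 fold change of -0.19 ± 0.55. With copies summed, no hypoxia or glycolysis gene was called over its list alone, and both lists kept a camera adjusted p under 0.05 with the preset correlation (2.4e-08 and 5.6e-06) and lost it with the estimated one (0.416 and 0.525).

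Single members of the hypoxia list had large spreads between mutants. ero1a, an endoplasmic reticulum oxidase gene, was at 151 ± 199 CPM in mutants and 14.0 ± 10.96 CPM in wild type, and ndrg1a was at 516 ± 749 and 66.8 ± 8.58 CPM. Both were highest in cxcr4a mutant 1, at 448 and 1637 CPM. pfkfb3, a regulator of glycolysis, had a log2 fold change of 1.59 ± 0.42 (edgeR adjusted p = 0.180) and vegfab, encoding an angiogenic ligand, 2.22 ± 0.72 (edgeR adjusted p = 0.287). The other ligand genes of the panel were at 0.40 ± 0.37 for vegfaa and -0.21 ± 0.38 for vegfc.

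**Figure D2:**
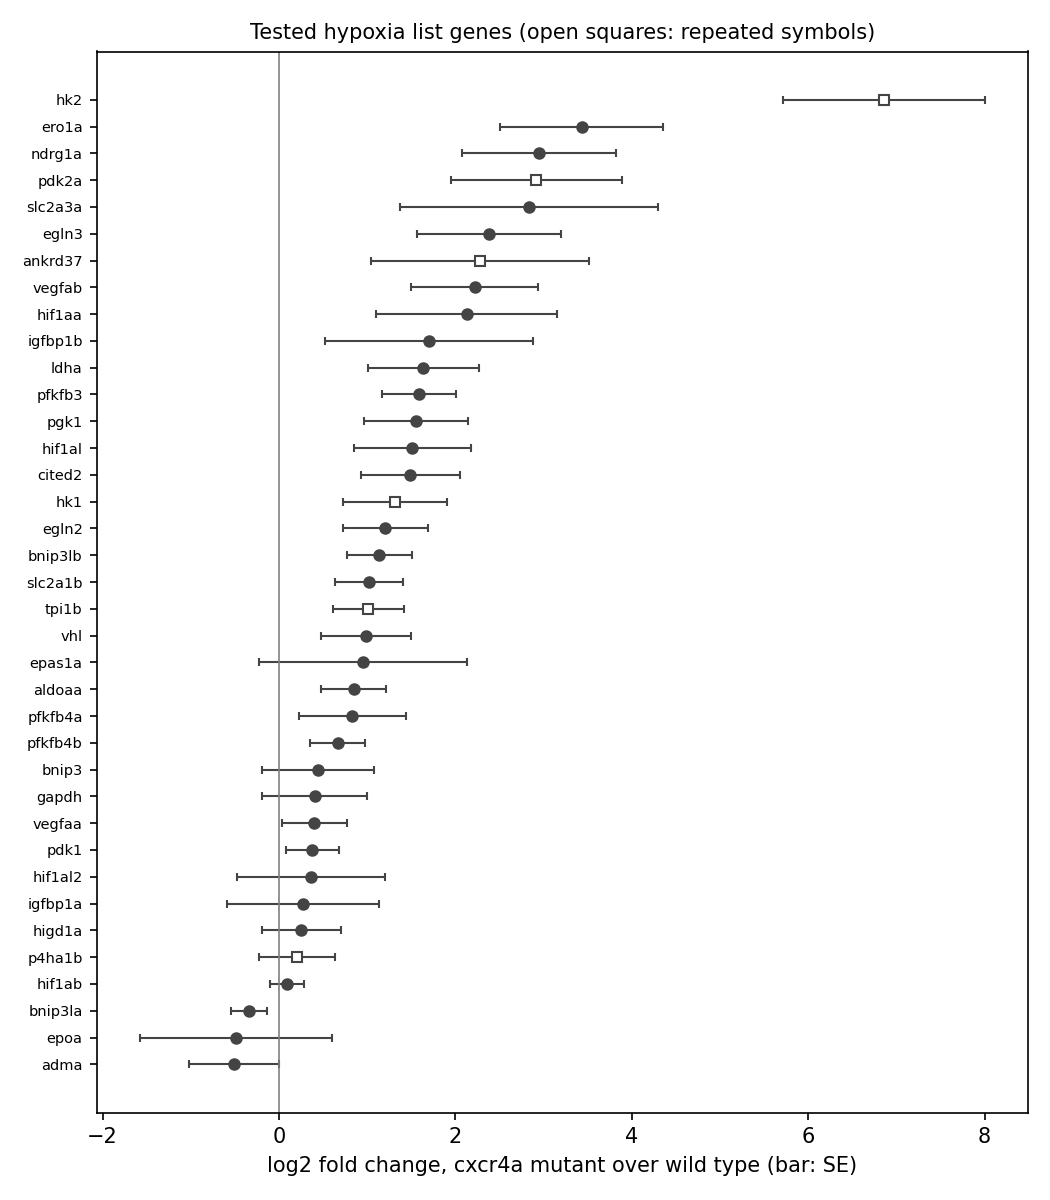
log2 fold change of each tested member of the hypoxia list in cxcr4a mutants over wild type, with SE, and open squares for repeated symbols. Of 37 members, 34 lie above 0, and hk2, a repeated symbol, has the largest value at 6.86.

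Inflammatory genes and matrix enzymes were also higher in mutants as lists. Of 31 tested inflammatory genes, 27 had positive changes (median 0.93, camera adjusted p = 4.6e-05; adjusted p = 0.589 with an estimated correlation), and 4 were called higher by edgeR when adjusted over the list alone against 0 over all genes (10 at an unadjusted p under 0.05; DESeq2 called 4 over all genes). These were cxcl8a, a neutrophil chemokine gene, the complement genes c3a.1 and c3a.2, and saa, an acute phase gene. saa reached 859 CPM in cxcr4a mutant 1 and at most 37.6 CPM in the other 3 mutants. Of 30 matrix remodelling enzymes, 24 were positive (median 0.59, camera adjusted p = 0.00122; adjusted p = 0.666 with an estimated correlation). Adjusted over the list alone, loxl2a and loxl2b, which encode enzymes that crosslink collagen, were called higher by edgeR and timp2a lower, against 0 over all genes (11 higher and 1 lower at an unadjusted p under 0.05; DESeq2 called 2 higher and 1 lower). With copies summed, edgeR called 3 inflammatory genes and no matrix enzyme gene over its list alone, and timp2a was at 0.03 ± 0.25. Both list scores were above every wild-type library in all 4 mutants, each with an exact permutation p of 0.0286 and 0.221 after adjustment. Without cxcr4a mutant 1 and 2, left out after seeing the data, the matrix enzyme list and the fibroblast list no longer passed (camera adjusted p = 0.0670 and 0.984).

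Another 4 lists were called higher with the preset correlation and not with the estimated one. Cardiomyocyte genes had 26 of 30 positive changes (median 1.04, camera adjusted p = 0.00160; adjusted p = 0.955 with an estimated correlation) and no member called by edgeR over the list alone or over all genes (7 at an unadjusted p under 0.05; DESeq2 called 4 over all genes). Their score was 5.58 in cxcr4a mutant 3 and 3.29 in cxcr4a mutant 1, below every wild-type library, and the list lost its call without cxcr4a mutant 3 (camera adjusted p = 0.144). Without cxcr4a mutant 1 and 2, left out after seeing the data, its camera adjusted p was 3.6e-23, against 1.4e-04 for the hypoxia list. Chemokines and receptors had 19 of 26 positive changes (camera adjusted p = 0.0202; adjusted p = 0.955 with an estimated correlation), and fibroblast and interstitial matrix genes 24 of 33 (camera adjusted p = 0.0202; adjusted p = 0.955 with an estimated correlation), among them fbn1. Angiogenic ligands and guidance genes had 27 of 39 (camera adjusted p = 0.0392; adjusted p = 0.589 with an estimated correlation). Adjusted over the list alone, they held 3 genes called higher, angptl2b, cxcl12a and apln (outside the naming rule and chosen after its values were seen), and pdgfd and cxcl12b called lower, against 0 over all genes by edgeR (10 higher and 3 lower at an unadjusted p under 0.05; DESeq2 called 4 higher and 2 lower). With copies summed, edgeR called 3 higher and 1 lower over that list alone. Leaving out single libraries ended the calls of these last 3 lists. Without cxcr4a mutant 1 the camera adjusted p values were 0.178, 0.270 and 0.0751, and without wild type 2 they were 0.0692, 0.180 and 0.0832. The chemokine list also lost its call without cxcr4a mutant 4 (0.0682) or wild type 4 (0.0540), the fibroblast list without wild type 1 (0.0535), and the angiogenic list without wild type 4 (0.0708). The stricter low-count filter also ended the chemokine and angiogenic calls (0.110 and 0.0615), and voom values the angiogenic one (0.0502).

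**Figure D3:**
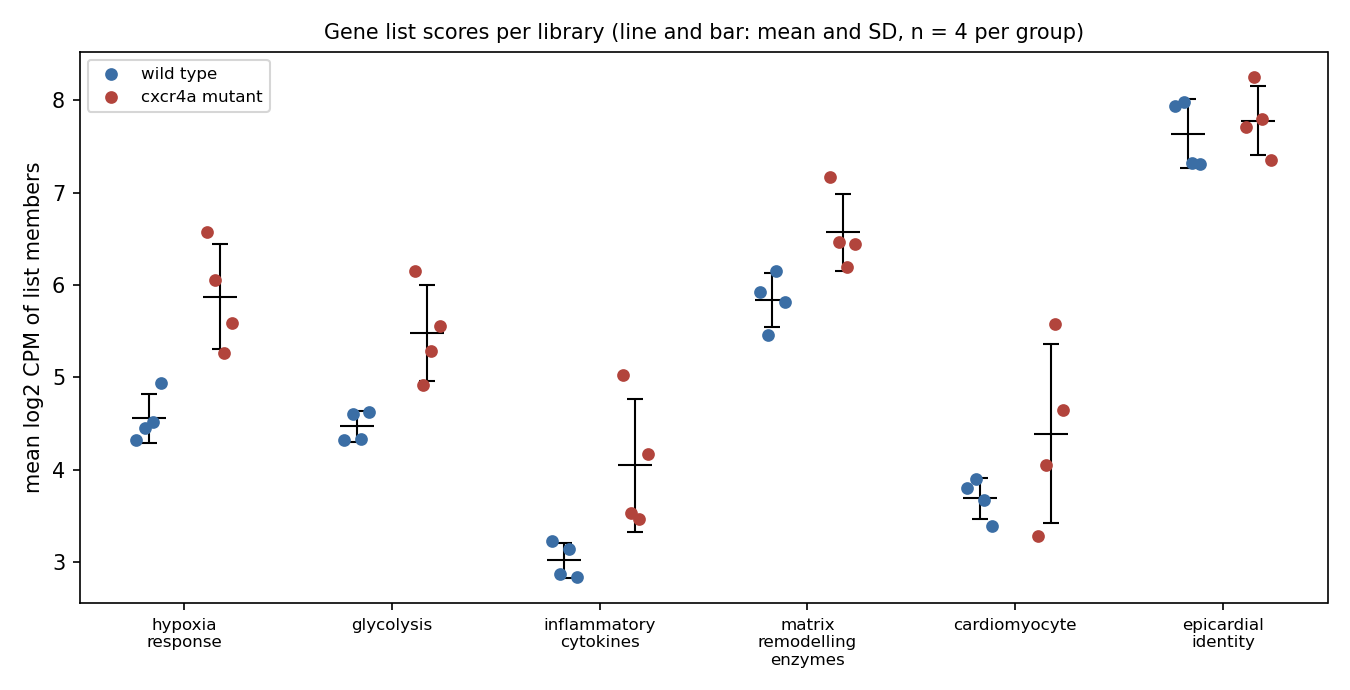
Scores of 6 gene lists (mean log2 CPM of list members) in each library, with mean and SD of 4 libraries per group. The hypoxia, glycolysis, inflammatory and matrix enzyme scores do not overlap between groups, while the cardiomyocyte and epicardial identity scores do.

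Epicardial identity genes showed no shift as a list (12 of 25 positive, camera adjusted p = 0.770). The plain copy of tcf21 had 71.7 ± 24.5 CPM in mutants and 81.7 ± 24.0 CPM in wild type, tbx18 had 747 ± 68.3 and 830 ± 279 CPM, and wt1b had 139 ± 44.4 and 105 ± 31.4 CPM (edgeR adjusted p = 0.890, 0.899 and 0.695). hapln1a, a hyaluronan linker gene, was at 2344 ± 875 and 1470 ± 707 CPM (edgeR adjusted p = 0.610). The repeated symbol aldh1a2 had 12 counts in all mutants and 15 in all wild types on its plain copy, 15 and 18 with copies summed, and was tested in neither fit. The scavenger receptor gene ackr3b (plain copy) was at 0.95 ± 0.52, the endothelial gene kdrl (plain copy) at -0.15 ± 0.49 and the cardiomyocyte gene myl7 at 1.25 ± 0.53 on the log2 scale (edgeR adjusted p = 0.573, 0.954 and 0.434). With copies summed, tcf21 was at -0.31 ± 0.26, ackr3b at 1.21 ± 0.46 and kdrl at -0.13 ± 0.49 (edgeR adjusted p = 0.793, 0.497 and 0.971).

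The remaining lists were not called by camera. Adjusted p was 0.108 for immediate early and dissociation genes and for TGF-beta and BMP signalling, and 0.160 for mural cell, mitochondrially encoded and Notch genes. It was 0.198 for Hippo and YAP targets and for nuclear oxidative phosphorylation, 0.261 for basement membrane, 0.298 for epicardial progenitor activation and 0.309 for paracrine growth factors. It was 0.472 for retinoic acid signalling, epithelial junctions and erythrocyte and thrombocyte genes, and 0.578 for interferon and antigen presentation and for leukocytes. It was 0.772 for the unfolded protein response, 0.789 for ribosomal proteins, 0.844 for the cell cycle, lipid and cholesterol, coronary endothelial and Wnt lists, and 0.996 for neural and Schwann cell genes. With copies summed, 3 of these lists were called higher with the preset correlation, immediate early and dissociation (camera adjusted p = 0.0170), TGF-beta and BMP (0.0452) and mural cell genes (0.00715), and each was lost with the estimated one (adjusted p = 0.830 with an estimated correlation). The mean and median of the changes differed in sign for leukocyte, unfolded protein response, lipid and epicardial identity genes. In the erythrocyte and coronary endothelial lists both were negative while camera ranked them higher.

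On the chromosome of cxcr4a, in the GRCz12tu assembly, 8 of 779 tested genes (1.03%) were called against 55 of 16422 elsewhere (Fisher's exact odds ratio 3.09, 95% interval 1.27 to 6.55, p = 0.00731). A different chromosome had a higher share, 14 of 997 (1.40%). Within 10 Mb of cxcr4a 7 of 228 were called (odds ratio 9.56, 95% interval 3.64 to 21.4, Fisher's exact p = 1.9e-05). All 7, named after their values were seen, were suffixed copies that fell in mutants: abcc4_1, dzip1_1, gcdha_1, slc44a2_1, vps16_1, zgc:64065_1 and zgc:112023_1. Each was placed by its plain symbol, so whether the copy itself lies there is not known. abcc4_1 had 0 counts in mutants and 641 in wild type and was at least 200-fold lower, and vps16_1, with 0 and 439 counts, was at least 137-fold lower. With copies summed, 0 of the 8 called symbols lay on that chromosome, and edgeR had 1437 symbols at an unadjusted p under 0.05 in that fit. Without wild type 1, 0 of 16 called genes lay there, and without cxcr4a mutant 1 or 3 the odds ratio for the chromosome was 0.960 or 0.925.

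Library measures did not differ between groups by more than the spread of libraries. The share of counts from mitochondrial rRNA was 4.89% ± 1.76 in mutants and 9.75% ± 8.26 in wild type (exact permutation p = 0.343), with 21.4% in wild type 1. Total count and the number of detected genes had exact permutation p of 0.543 and 0.971, and the shares of mitochondrial mRNA and of the 10 most abundant genes had 0.714 and 0.629.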

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

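No test here was chosen after the results were seen. Single libraries that stood apart from the other 3 of their group were found in 33 of 360 group checks. The cutoff gives about 1 in 20 for independent, normally distributed values. Most checks used unlogged CPM of named genes, so that rate does not apply and no excess of flags can be read from the 33. The flags for eif2ak3, ubtd2_1 and parp14rs4 rest on 1 or 2 counts. Of the 33 flags, 12 were in cxcr4a mutant 1, and their cause was not tested.

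In cxcr4a mutant 1, 12 genes were highest of their group: ero1a at 448 CPM, ndrg1a at 1637, slc16a3b at 344, saa at 859, mmp9 at 185, serpine2 at 918, inhbaa at 198, grna.1 at 125, cxcl12a at 360, cldn5a at 58.1, rxrab at 7.82 and rimkla at 1.63 CPM. The hypoxia list kept its call without this library (camera adjusted p = 9.7e-08 with the preset correlation), as did the inflammatory list (0.00434). With all libraries and an estimated correlation neither list was called (adjusted p = 0.589 with an estimated correlation for both).

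In cxcr4a mutant 2, hey2 was at 46.3 CPM, rgs5a at 2.56 and ubtd2_1 at 0.0570 CPM, and the epithelial junction score was 6.34. In cxcr4a mutant 3, elavl4 was at 17.2 CPM, jag1a at 19.04 and c3a.2 at 1.48 CPM, and the interferon and antigen presentation score was low at 3.61. In cxcr4a mutant 4, nr4a3 was at 130 CPM and parp14rs4 at 0.0693 CPM, and the unfolded protein response score was 6.51.

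In wild type 1, bdnf was at 0 CPM and eif2ak3 at 0.106 CPM. In wild type 2, fbln1 was at 3.06 CPM and vegfc at 50.9 CPM. In wild type 3, hey2 was at 4.58 CPM, nr4a3 at 39.6 and rgs5a at 205 CPM. In wild type 4, f3a was at 7.24 CPM, and the coronary endothelial and Notch scores were low at 2.01 and 3.095.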

How the results depend on the processing

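Summed copies, no mitochondrial genes, and the lists without cxcr4a mutant 1 and 2 were chosen after the results were seen. Genes called numbered 901 with DESeq2, 100 with voom and quality weights, 41 with the stricter low-count filter and 63 with edgeR. The DESeq2 calls were 482 higher and 419 lower, so most were higher, whereas most edgeR calls were lower. Leaving out 1 library at a time gave 16 to 43. Summing copies gave 8. Limma voom (58), DESeq2 size factors (63), library size only (62), no low-count filter (75), the fold threshold (59) and no mitochondrial genes (62) gave similar numbers.

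The replicate number as a block, or pairing, left 2 called genes; ccr11.1 and mhc2dhb lost their calls, as did the fibroblast and angiogenic lists (camera adjusted p = 0.0892 for both). Same-number libraries correlated at 0.0741, 0.0675, 0.0672 and -0.0752 for replicates 1 to 4. Libraries with different numbers ranged from -0.106 to 0.183, the highest being cxcr4a mutant 4 with wild type 3. These correlations do not settle whether the numbers mark pairs.

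Summing copies reversed the sign of single copies: log2 fold changes became -0.21 for rpia, -0.32 for lamtor5, 0.13 for bmp2k_1, 0.17 for gstt1b_1, 0.31 for rimkla, -0.19 for hk2, 1.19 for f3a, 0.15 for klf2a, 0.0349 for timp2a, 0.24 for rgs4, 0.0122 for rgs5a and 0.0165 for rpl5b.

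Called lists fell from 8 to 0 with an estimated correlation in camera (1 at an unadjusted p under 0.05) and to 0 with the directional fry test (5 at an unadjusted p under 0.05). The mixed fry test, which ignores direction, called 4. With copies summed 11 were called, the 8 and immediate early and dissociation, TGF-beta and BMP, and mural cell genes. None of the 11 passed with copies summed and an estimated correlation, where the smallest camera adjusted p was 0.416. Leaving out 1 library gave 5 to 14. Without cxcr4a mutant 1 and 2, cell cycle, leukocyte and ribosomal protein genes changed direction with camera adjusted p of 0.0131, 0.00112 and 1.4e-04. Over left-out libraries, coronary endothelial genes ranged from 0.0304 (without wild type 4) to 0.772 (without cxcr4a mutant 4), with direction changed in both and without cxcr4a mutant 3. The cause was not tested.

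The odds ratio on the chromosome of cxcr4a was 0 to 4.15 when 1 library was left out and 0 with copies summed. Within 10 Mb it was 0 to 12.6, 0 with copies summed and 1.41 with DESeq2.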

Other observations

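Tests of summed copies, of partner copies and of the hypoxia score adjusted for marker scores were chosen after the results were seen. The counts over splits and the test around cxcr4a were written before. The summed copies that were also counted over splits were themselves chosen after seeing the data.

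Some groups not called as lists held members called when adjusted over the list alone. In retinoic acid signalling, rxrba, a nuclear receptor gene, and crabp2a, a retinoic acid binding protein gene, had log2 fold changes of 1.01 ± 0.19 and 2.07 ± 0.52 in cxcr4a mutants (0.0119 and 0.0367 over the list alone with edgeR, 0.0699 and 0.154 over all genes). That list had 15 positive and 12 negative changes, with 2 higher and 3 lower at an unadjusted edgeR p under 0.05. DESeq2 called 3 of its members higher and 1 lower over all genes. In the lipid list abca1a was at 1.58 ± 0.29 (0.0106 over the list alone, 0.0638 over all genes). In the mural list abcc9 and rgs5b were at 1.24 ± 0.32 and 2.27 ± 0.62 and the plain copies of rgs4 and rgs5a at -3.46 ± 0.84 and -6.41 ± 1.56, and these 4 and ndufa4l2a (4.90 ± 1.58), chosen after its values were seen, were under 0.05 over the list alone and none over all genes with edgeR (5 higher and 2 lower at an unadjusted p under 0.05), while DESeq2 called 3 higher and 1 lower over all genes. The rgs4 and rgs5a copies summed to 0.24 and 0.01, and with copies summed edgeR called 2 mural genes higher and 0 lower over the list alone. As deposited, the immediate early and dissociation, Hippo and YAP, and coronary endothelial lists each had 1 member called lower over the list alone. The basement membrane, leukocyte and unfolded protein response lists each had 1 called higher.

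The number of called genes was unusual among groupings of these libraries. Of the 35 splits of the 8 libraries into 4 and 4, 1, the real one, gave as many as 63 genes with edgeR, and the highest other gave 1. With copies summed the real split again was the 1 with as many, with 8 symbols against 1 in the highest other. For DESeq2 it was also 1, with 901 genes against 430 in the highest other and a median of 28.5 among the others. For these 3 counts the real split was the highest, and 35 splits can give no stronger result. The other splits mix genotypes, so a genotype difference adds to their spread within groups and can lower their counts. The counts of the real split stand above all others, but chance is not excluded by them. The number of called lists was not unusual: 33 of the 35 splits gave 8 or more, and the highest other gave 20, so chance cannot be excluded for it. The other splits had a median of 13.5 called lists, more than the real one.

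In the first pattern, of 39 called copies with a tested partner, 92.3% had a partner that moved the opposite way, against 61.0% of 1359 pairs with no call (Fisher's exact p = 3.1e-05). For antxr2a and bmp2k both copies were called, so these pairs enter the 39 in both orders, while pairs with no call were not repeated. The 41 called copies belong to 39 symbols, whose median absolute log2 fold change after summing was 0.321 (bootstrap 95% interval 0.194 to 0.546) against 6.37 as deposited, which argues against a change of the whole gene for most of them. The exceptions include parp14rs4 and clic2_2, whose other copies were not tested: parp14rs4 was still called after summing, and clic2 kept its log2 fold change (-5.12 as deposited, -5.06 ± 0.74 summed) but not its call (edgeR adjusted p = 0.0719). A candidate explanation is that the genotypes carry different haplotypes of these genes, whose reads are placed on different copies. Genotype and background cannot be separated for these copies or for the other called genes. The breeding of the fish is not given in the sources used here.

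The second pattern is the excess of calls around cxcr4a, with an odds ratio of 3.09 on its chromosome. A haplotype carried with the mutant allele may account for it, but the test cannot settle this. All 8 calls there are repeated symbols, and the 7 placed within 10 Mb were lower in mutants. Fisher's exact test was not restricted to repeated symbols, so a region rich in them could give the same excess. A linked haplotype does not account for the 33 repeated calls that their plain symbols place on other chromosomes. Of these chromosomes, 1 had a higher share of called genes (1.40% against 1.03%), with 14 calls, 12 of them repeated symbols. The excess on the chromosome rests on few genes, no longer passed Fisher's exact test when any library other than cxcr4a mutant 2 was left out, and was lost with copies summed, where 8 calls leave a 95% interval up to 13.2 for the odds ratio. A response to the mutation at the neighbouring genes was not tested.

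The third pattern is the higher hypoxia score in cxcr4a mutants, a difference of 1.32 (95% interval 0.55 to 2.09). Adjusted for the cardiomyocyte score in a linear model over 8 libraries the difference was 1.74 (1.44 to 2.04). Adjusted for the immediate early and dissociation score it was 1.18 (0.32 to 2.05). These values argue against cardiomyocyte RNA or dissociation stress, as read by these scores, as the whole cause. Among mutants the hypoxia score fell as the cardiomyocyte score rose, from 6.58 at 3.29 (cxcr4a mutant 1) to 5.27 at 5.58 (cxcr4a mutant 3). The larger difference after cardiomyocyte adjustment reflects this inverse relation, so the hypoxia score was not independent of the cardiomyocyte score. Adjusted for the leukocyte score the difference was 1.30 (0.43 to 2.16), and for the mural cell score 1.29 (0.51 to 2.07). These were among 20 models computed over 4 lists. In 3 of the others, for inflammatory genes and matrix enzymes, the interval included 0. Adjusted for the dissociation score, the difference was 0.98 (-0.15 to 2.11) for inflammatory genes and 0.61 (-0.07 to 1.30) for matrix enzymes. Inflammatory genes adjusted for the mural cell score were at 1.04 (-0.02 to 2.09). Dissociation stress is thus not argued against for these 2 lists. With copies summed the dissociation list was itself called higher (camera adjusted p = 0.0170), though not with an estimated correlation (0.830). Causes other than those read by these scores were not tested. The hypoxia list lost its call with an estimated correlation (0.589). Among the other splits of the libraries camera gave it smaller unadjusted p values, 5.6e-18 and 1.4e-11, than the 5.5e-11 of the real one. Those splits grouped wild type 4 with cxcr4a mutants 1, 2 and 4 and with cxcr4a mutants 1, 2 and 3. They hold part of the real difference, so they do not measure chance alone. Chance is not excluded for the hypoxia list either.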
